A study of Mus musculus with 36 samples.

How the data were processed

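Per the labels, kidneys came from mice given CdCl2 at 0, 0.5 or 2 mg/kg, total RNA was taken with TRIzol, and RNA with an integrity number above 6.5 was used for mRNA libraries. The labels give neither route, duration nor sex. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with Trimmomatic, checked with FastQC and aligned to GRCm38 with STAR. Per the file headers, reads per gene were counted with featureCounts 1.4.6-p2 against the Ensembl 96 annotation with its default settings, which ignore strand. The deposited values are whole read counts per gene, 1 column for each of the 36 libraries. The series also holds 1 joined table of counts, and its 36 columns were not used here.

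All 55536 gene identifiers matched the GENCODE M21 annotation of GRCm38 with the same start and end, and symbols and positions were taken from it. CPM, log2 changes and every p-value were computed here from the deposited counts. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Genes were kept by the default expression filter of edgeR for the 6 groups (18180 genes), libraries were scaled by trimmed mean of M values (factors 0.892 to 1.122), and 1 quasi-likelihood model with a mean per group was fitted to the 36 libraries (common dispersion 0.0489). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within each of 9 comparisons: ob against b6j controls, each dose against control and the doses against each other in each genotype, and the difference between genotypes in the response to each dose. Standard errors are the log2 change over the root of the quasi-likelihood F statistic. CPM used the scaled library sizes. With 26783936 to 37244058 counted reads per library, 3 counts are worth 0.081 to 0.112 CPM, and levels below that are read as near absent.

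Fixed gene lists, 39 with 682 symbols of which 2 are not in the annotation, were written from general knowledge of kidney cells and stress pathways before the data were examined, as were the main test, the threshold and the alternatives named last. Lists were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data, a far stricter test. Counts adjusted over the list alone repeat the adjustment among the members only.

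Genes named in the text were chosen by rule: Mt1, Mt2, Havcr1, Lcn2, Hmox1 and Lep in each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, and up to 4 members with the smallest p of a list described. Genes whose call hung on many single libraries, some that start below the CPM worth of 3 counts, and a few others were left out. Members of short groups of called genes were named in full, and a few genes were carried to other comparisons.

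On simulated counts drawn from the means and library sizes of these 36 libraries, with 200 genes changed in a group, the edgeR test found 90.4% of genes changed 2-fold in b6j at 0.5 mg/kg, 90.1% in ob at 0.5 mg/kg and 79.3% for the interaction at 0.5 mg/kg, each over 17912 genes and 5 simulated sets. Of genes changed 1.5-fold it found 50.7%, 71.2% and 44.1%. The 200 genes were picked at random, separately for each genotype, among those with an average log2 CPM above 0. In ob and the interaction the 1.5-fold genes also held the raised lysosome genes described below. So 50.7% and 71.2% do not compare the genotypes. No simulated library was set apart from its group as a whole. Unchanged genes made up 4.13%, 4.96% and 4.96% of its calls. Raising the 24 lysosome genes 1.5-fold in ob at 0.5 mg/kg was found by camera in 5 of 5 sets, and 0 of 190 tests of other lists were called. Scaling decides where the centre of all genes lies: with library size alone the median log2 change of all genes was 0.161 between control groups, 0.119 in b6j at 2 mg/kg, -0.11 in ob at 0.5 mg/kg and 0.124 between the doses in ob, against 0.026, 0.017, -0.01 and 0.021 with the scaling used.

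Alternatives planned beforehand were DESeq2, limma-voom with sample weights, another scaling, no filter and a stricter one, a fit to the compared groups alone, replicate number as a block, each library left out in turn, and controls divided between doses. Values without ob_Cd2 replicate 5 as a lead count and values without b6j_control replicate 4 were chosen after seeing the data. Groups were also exchanged at random between libraries, first in 40 ways. For the interaction at 2 mg/kg 2 of those 40, the real one included, called as many genes, which met the bound for chance of 5% or more. After that was seen the number was raised to 100.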

Results

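Kidneys of 36 mice were sequenced to ask 3 things about cadmium: which kidney transcripts move with the dose of CdCl2, whether obese ob/ob mice (ob) respond as C57BL/6 mice (b6j) do, and how the kidneys of the 2 genotypes differ before any cadmium. Each genotype was given 0, 0.5 or 2 mg/kg, with 6 mice and 6 libraries in each of the 6 groups. The libraries held 26783936 to 37244058 counted reads. Of 55536 annotated genes, 20448 had no count in any library and 18180 were tested. All calls come from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment across those 18180 genes. Changes are log2 ratios ± standard error, and levels are in CPM as mean ± standard deviation of 6 mice.

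The first principal component held 28.2% of the variance and followed dose. Along it ob_Cd2 replicate 5 stood highest, at 135.91, with the next library at 69.12. The third held 8.7% and set ob controls apart from b6j controls. The second held 12% and had a single library, ob_Cd2 replicate 5, far out at 132.02 while the other 35 lay between -31.75 and 17.65. Along it those others fell with dose, from 11.35 to 17.58 in b6j controls to -29.6 to -16.41 in b6j mice at 2 mg/kg. All 6 replicates of every group were kept. Values without that library are given for gene and list counts, for named genes whose call it decides or whose value it moves by more than 1.5 times, and for lists that lose their call.

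**Figure D1:**
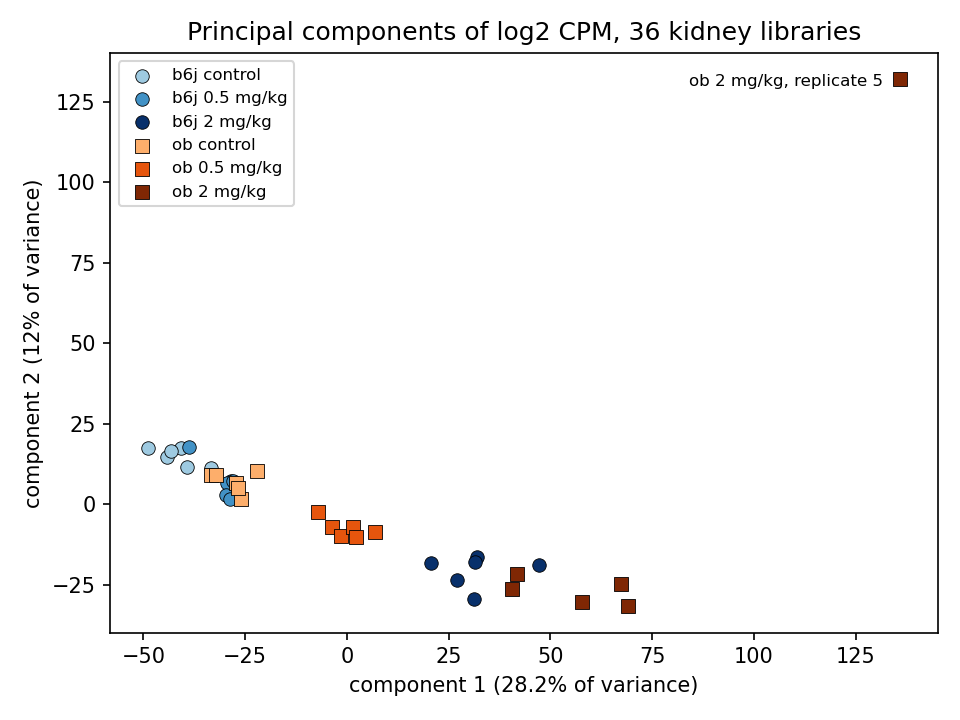
Scores of the 36 libraries on the first and second principal components of log2 CPM. Shade marks dose and shape marks genotype.

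Transcripts of the Y-linked gene Ddx3y lay between 37.4 and 98.7 CPM and Xist never passed 1.83 CPM, so all 36 libraries read as male. Lep, the gene altered in ob/ob mice, was at 3.43 ± 3.08 CPM in ob controls and at 0.0716 ± 0.0734 CPM in b6j controls (log2 difference 5.47 ± 1.17, adjusted p = 0.000929, 5 of 6 ob controls above every b6j control). The b6j level is below the CPM worth of 3 counts, 0.081 to 0.112 by library, so only the direction of that difference is used, and with limma-voom it was not called, at 4.79 (adjusted p = 0.123). No change of Lep with cadmium was called in either genotype. The log2 change was 0.98 (adjusted p = 1) and 1.35 (adjusted p = 0.53) in b6j at 0.5 and 2 mg/kg. In ob it was -0.15 (adjusted p = 0.969, or -1.98 and still not called without ob_Cd0.5 replicate 2) and -0.78 (adjusted p = 0.495). Lep is also on the fixed list of perirenal fat genes. The mean log2 score of that list ran from -2.743 to 1.547 in ob controls and from -1.318 to 1.043 in b6j controls. It was 2.018 in ob_Cd0.5 replicate 2, where Lep was at 14.1 CPM. Fat left on the kidney was not separated from the kidney itself, so Lep is not read as a kidney transcript.

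Positions of the protein-coding genes followed most closely are on GRCm38. They are Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568), Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) and Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877). Further ones are Gstm3 (ENSMUSG00000004038, chromosome 3, 107963696 to 107969283), Ugt2b35 (ENSMUSG00000035811, chromosome 5, 87000860 to 87013275), Cyp24a1 (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145), Prlr (ENSMUSG00000005268, chromosome 15, 10177238 to 10349180), Slc22a7 (ENSMUSG00000067144, chromosome 17, 46432183 to 46438457) and Ccl28 (ENSMUSG00000074715, chromosome 13, 119623819 to 119654359). Counting ignored the strand, so genes with an antisense neighbour and families of close copies, among them the Ugt1a, Ugt2b, Gst, metallothionein and Cyp4a12 genes, may trade reads between members.

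Before cadmium, ob kidneys carried far more prolactin receptor and far less of the organic anion transporter Slc22a7 than b6j kidneys. Prlr stood at 113 ± 16.4 CPM in ob controls and 6.05 ± 4.40 CPM in b6j controls (18.7-fold higher, log2 4.22 ± 0.35, adjusted p = 6.26e-11, 6 of 6 ob libraries above every b6j library). Slc22a7 stood at 2.5 ± 1.4 and 197 ± 57.5 CPM (79.2-fold lower, log2 -6.31 ± 0.36, adjusted p = 6.47e-15, 6 of 6 libraries below). The chemokine Ccl28 was also scarce in ob controls, at 2.31 ± 0.783 against 36.4 ± 18.3 CPM (log2 -3.98 ± 0.31, adjusted p = 1.77e-11). Other genes higher in ob controls were the amino acid transporter Slc7a12 (3.78 ± 0.54), kynureninase Kynu (3.53 ± 0.45) and Bhmt (2.91 ± 0.42). Lower in ob were Akr1c18 (-4.54 ± 0.39), Mfsd2a (-3.05 ± 0.34) and the close copies C4a (-3.59 ± 0.36) and Cyp4a12a (-3.23 ± 0.26). The members Ugt1a2 (6.67 ± 0.70) and Ugt1a10 (5.10 ± 0.37) read as the largest gains among genes with a mean of at least 5 CPM, with the caution that exons shared within that locus make the split between members uncertain.

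Metallothionein did not differ between untreated genotypes (Mt1 -0.06 ± 0.13, adjusted p = 0.837, and Mt2 0.11 ± 0.32, adjusted p = 0.868), and neither did Lcn2 (-0.09 ± 0.78, adjusted p = 0.964). Hmox1 was lower in ob controls (-0.78 ± 0.16, adjusted p = 0.00073, 6 of 6 below every b6j control). Havcr1, which encodes the injury marker KIM-1, was at 0.831 ± 0.238 CPM in ob and 34.9 ± 71.5 CPM in b6j controls (-5.38 ± 0.92, adjusted p = 5.4e-05). The spread in b6j came from a single mouse, b6j_control replicate 4 at 180.6 CPM, and without it the difference was -2.78 (adjusted p = 0.00109). Cyp4a14 was higher in ob (2.95 ± 0.72, adjusted p = 0.00369), and 3.66 (adjusted p = 0.000942) without b6j_control replicate 5. Havcr1 (-3.15, adjusted p = 0.0559) was not called with limma-voom.

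In all, 2822 of 18180 genes differed between untreated ob and b6j kidneys, 1199 higher and 1623 lower in ob, and 468 of them by more than 2-fold. Leaving out ob_Cd2 replicate 5, which is in neither of these groups but enters the gene filter and the shared model, raised the count to 4781 (2166 higher, 2615 lower, 570 above 2-fold).

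Of 39 gene lists fixed beforehand, 12 differed between the control groups with a preset correlation between genes and 3 kept their call with an estimated correlation. The androgen-responsive kidney genes were lower in ob: 8 of 10 members fell and none rose (0 higher and 8 lower adjusted over the list alone, median log2 change -1.27, adjusted p = 1.35e-15, and adjusted p = 0.000445 with an estimated correlation), among them Cyp4a12a (given above), Cyp7b1 (-2.36 ± 0.29), Odc1 (-2.14 ± 0.23) and Gusb (-1.18 ± 0.10). Podocyte genes were higher, 8 of 11 (median log2 change 0.59, 8 higher and 0 lower adjusted over the list alone, adjusted p = 7.14e-09 or adjusted p = 0.00801 with an estimated correlation), among them Cdkn1c (0.86 ± 0.10), Podxl (0.59 ± 0.08) and Synpo (0.56 ± 0.08). Heat shock genes were lower, 6 of 15 (median log2 change -0.34, 0 higher and 8 lower adjusted over the list alone, adjusted p = 1.89e-05 or adjusted p = 0.022 with an estimated correlation), among them Hsp90aa1 (-0.70 ± 0.10), Hsp90ab1 (-0.62 ± 0.09) and Hspd1 (-0.42 ± 0.09).

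The other 9 lists were called with the preset correlation only, and where 2 adjusted p stand together the second is with an estimated correlation. Sterol synthesis had 12 of 24 members lower in ob (0 higher and 14 lower adjusted over the list alone, median log2 change -0.43, adjusted p = 7.14e-09, and adjusted p = 0.304 with an estimated correlation), with Idi1 at -1.49 ± 0.26 and Mvd at -0.95 ± 0.12. Endothelial genes had 8 of 14 higher (median log2 change 0.45, 10 higher and 0 lower adjusted over the list alone, adjusted p = 7.58e-07 or adjusted p = 0.365 with an estimated correlation), with Kdr at 0.60 ± 0.11 and Pecam1 at 0.52 ± 0.10. Matrix genes had 7 of 26 higher and 1 lower (adjusted p = 0.0106, or adjusted p = 0.801 with an estimated correlation), with Sparc at 0.53 ± 0.10 and Col5a2 at -1.20 ± 0.19. Mesangial and pericyte genes had 5 of 12 higher (adjusted p = 0.0106 or 0.304), with Itga8 at 1.10 ± 0.22. Urothelial genes had 4 of 9 higher (adjusted p = 0.00963 or 0.801), with Upk1a at 1.38 ± 0.40. Unfolded protein response genes had 6 of 23 lower (adjusted p = 0.00943 or 0.507), with Calr at -0.46 ± 0.07. Nuclear-encoded respiratory chain genes had 6 of 32 lower (adjusted p = 0.0176 or 0.945), with Cycs at -0.44 ± 0.10.

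NRF2 and glutathione genes had 7 of 25 higher and 3 lower, and although the test placed the list up (adjusted p = 0.0379, or adjusted p = 0.945 with an estimated correlation) its median was -0.02. Abcc4 (2.24 ± 0.16), Gsta2 (1.66 ± 0.15) and Gsta4 (1.45 ± 0.20) were higher in ob controls and Gclm (-0.69 ± 0.11) lower. Proximal tubule genes had 10 of 32 lower and 1 higher (median log2 change -0.09, adjusted p = 0.0445, or adjusted p = 0.948 with an estimated correlation), with Kap at -1.36 ± 0.33, Cyp4b1 at -0.85 ± 0.22 and Slc22a6 at -0.76 ± 0.17. With ob_Cd2 replicate 5 left out, 15 lists passed with the preset correlation. Leaving it out with an estimated correlation ended the call of the heat shock (adjusted p = 0.0773) list.

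**Figure D2:**
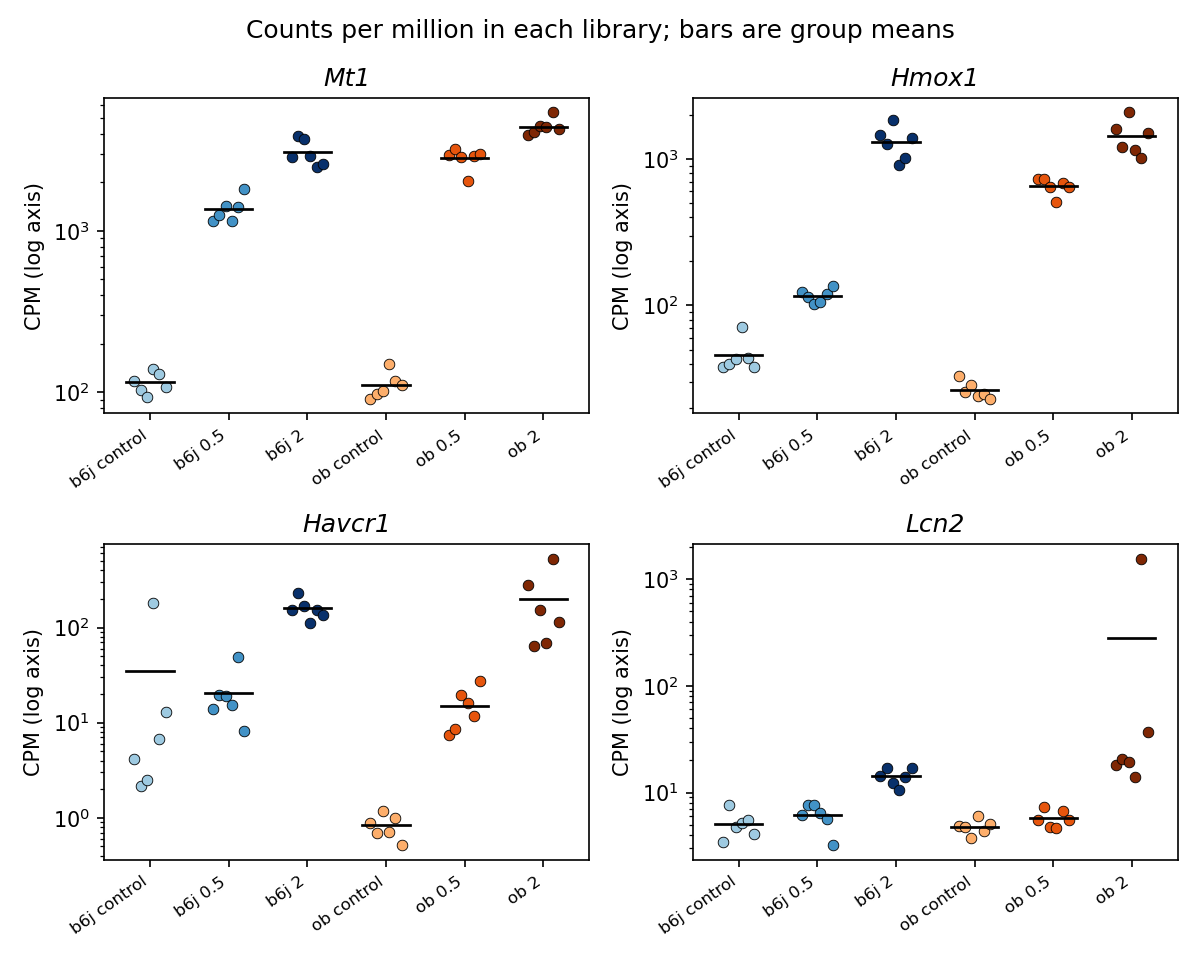
CPM of Mt1, Hmox1, Havcr1 and Lcn2 by genotype and dose in mg/kg, on log axes. Each point is 1 mouse and each bar the mean of a group.

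At 0.5 mg/kg, b6j kidneys made a narrow response centred on metallothionein. Mt1 rose from 116 ± 17.3 to 1369 ± 253 CPM (11.9-fold, log2 3.57 ± 0.15, adjusted p = 2.63e-19, 6 of 6 treated mice above every control). Mt2 rose by 3.85 ± 0.27 (adjusted p = 2.38e-12). Hmox1 rose from 45.7 ± 12.9 to 117 ± 12 CPM (1.35 ± 0.16, adjusted p = 2.36e-06, 6 of 6 above). The glutathione transferase Gstm3 rose from 0.203 ± 0.0896 to 1.23 ± 0.474 CPM (2.57 ± 0.47, adjusted p = 0.00277). Ugt2b35 rose from 0.133 ± 0.0631 to 1.08 ± 0.361 CPM (2.98 ± 0.62). The carboxylesterase Ces1g (1.93 ± 0.27), the scavenger receptor Stab2 (1.92 ± 0.23) and Nyx (2.54 ± 0.43) rose as well. Ugt1a2 rose by 3.80 ± 0.77 (adjusted p = 0.0102), a call that ended without b6j_Cd0.5 replicate 5, at 3.02 (adjusted p = 0.0953). The injury markers were not called. Havcr1 was at -0.75 ± 0.69 (adjusted p = 1), with the sign set by b6j_control replicate 4, without which it was 1.86 (adjusted p = 0.128), and Lcn2 at 0.27 ± 0.77 (adjusted p = 1). Gstm3 (2.40, adjusted p = 0.332), Ugt1a2 (3.68, adjusted p = 0.372) and Ugt2b35 (2.85, adjusted p = 0.347) were not called with limma-voom. Nyx (2.53, adjusted p = 0.0524) was not called with the compared groups alone.

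Called genes numbered 59 of 18180 genes, 54 higher and 5 lower, and 36 changed by more than 2-fold. Leaving out ob_Cd2 replicate 5 raised the count to 157 (127 higher, 30 lower, 54 above 2-fold). The share of called genes that rose was 91.5%, against 50.4% with limma-voom sample weights and 67.5% with a fit to the compared groups alone, so the balance of rises and falls is not settled. With the model unchanged, leaving out ob_Cd2 replicate 5 turned 54 higher and 5 lower into 127 and 30, so that library moves the balance. The fit to the compared groups leaves it out too, and limma-voom gave it a weight of 0.033. What the choice of model adds was not tested. The 5 lower genes were Ccl28 (-1.58 ± 0.27, adjusted p = 0.00124), the zinc importer Slc39a10 (-0.77 ± 0.13, adjusted p = 0.000633), Wdr90 (-0.41 ± 0.09), Cox7a2 (-0.32 ± 0.07) and Dock5 (-0.28 ± 0.06). The last 3 calls are fragile. Wdr90 was lost without b6j_control replicate 1 (-0.36, adjusted p = 0.143), b6j_control replicate 2 (-0.39, adjusted p = 0.083), b6j_control replicate 6 (-0.39, adjusted p = 0.0872), b6j_Cd0.5 replicate 1 (-0.38, adjusted p = 0.1), b6j_Cd0.5 replicate 4 (-0.41, adjusted p = 0.0579), b6j_Cd0.5 replicate 5 (-0.38, adjusted p = 0.118). Cox7a2 was lost without b6j_control replicate 2 (-0.29, adjusted p = 0.0725), b6j_control replicate 3 (-0.30, adjusted p = 0.0724), b6j_Cd0.5 replicate 1 (-0.31, adjusted p = 0.0543), b6j_Cd0.5 replicate 3 (-0.30, adjusted p = 0.0568), b6j_Cd0.5 replicate 4 (-0.29, adjusted p = 0.0709), b6j_Cd0.5 replicate 6 (-0.30, adjusted p = 0.0542). Dock5 was lost without b6j_control replicate 1 (-0.27, adjusted p = 0.115), b6j_control replicate 3 (-0.27, adjusted p = 0.0927), b6j_control replicate 4 (-0.29, adjusted p = 0.0553), b6j_control replicate 5 (-0.28, adjusted p = 0.0677), b6j_Cd0.5 replicate 2 (-0.26, adjusted p = 0.134), b6j_Cd0.5 replicate 5 (-0.25, adjusted p = 0.14), b6j_Cd0.5 replicate 6 (-0.27, adjusted p = 0.0888). Dock5 (-0.29, adjusted p = 0.0617) was not called with the compared groups alone.

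Of the 39 lists, 12 passed with the preset correlation and 2 with an estimated one. Metal handling genes had 2 of 15 members higher and 1 lower (3 higher and 1 lower adjusted over the list alone, median log2 change 0.12, adjusted p = 9.42e-16, and adjusted p = 6.65e-08 with an estimated correlation). NRF2 and glutathione genes had 5 of 25 higher (median log2 change 0.14, 8 higher and 0 lower adjusted over the list alone, adjusted p = 4.45e-16 or adjusted p = 0.046 with an estimated correlation), with Gsta4 at 1.37 ± 0.20, Abcc4 at 1.14 ± 0.15 and Gsta2 at 0.94 ± 0.14. The other 10 lists held at most 1 called gene, and their adjusted p lay between 0.289 (lysosome) and 0.956 (tubular injury) with an estimated correlation. The preset correlation gave 13 lists without ob_Cd2 replicate 5. With an estimated one, its removal ended the call of the NRF2 and glutathione (adjusted p = 0.145) list.

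The same low dose moved ob kidneys further. Mt1 rose from 111 ± 21.2 to 2823 ± 408 CPM (25.4-fold, log2 4.67 ± 0.15, adjusted p = 1.91e-22, 6 of 6 above every control) and Mt2 by 4.90 ± 0.26. Hmox1 rose from 26.6 ± 3.73 to 655 ± 81.3 CPM (24.6-fold, log2 4.62 ± 0.19, adjusted p = 1.06e-19, 6 of 6 above). Gstm3 went from 0.271 ± 0.143 to 25.3 ± 6.77 CPM (6.51 ± 0.38) and Ugt2b35 from 0.184 ± 0.160 to 35.2 ± 11.6 CPM (7.56 ± 0.45). Popdc3 went from 0.0148 ± 0.0363 CPM, with reads in 1 of 6 controls, to 4.62 ± 1.45 CPM. Its fitted change is 7.91 ± 0.77, or 10.16 without ob_control replicate 4, and has no firm size from so low a start. Gsta1 (5.25 ± 0.53), the angiotensin (1-7) receptor Mas1 (4.75 ± 0.41), the interleukin 1 antagonist Il1rn (2.96 ± 0.61), carbonyl reductase Cbr3 (2.53 ± 0.20) and Gdf15 (2.37 ± 0.26) rose with them.

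KIM-1 transcript was raised in ob kidneys at this dose, with Havcr1 going from 0.831 ± 0.238 to 15.1 ± 7.54 CPM (4.17 ± 0.91, adjusted p = 0.00325, 6 of 6 above every control). This did not place ob above b6j mice at the dose: the Havcr1 level differed by -0.46 (ob minus b6j, adjusted p = 0.784). Lcn2 was not called (0.26 ± 0.78, adjusted p = 0.936). Among the genes that fell were Slc39a10 (-1.03 ± 0.13, adjusted p = 5.56e-07), Pla2g7 (-0.91 ± 0.21), Dusp1 (-0.75 ± 0.17) and thymidine kinase Tk1 (-0.65 ± 0.15). The call covered 779 of 18180 genes, 645 higher and 134 lower, 235 of them by more than 2-fold. Without ob_Cd2 replicate 5 it covered 1780 genes (1222 higher, 558 lower, 302 above 2-fold). The share of called genes that rose was 82.8%, against 67% with limma-voom sample weights and 65.7% with a fit to the compared groups alone, so the balance of rises and falls is not settled. With the model unchanged, leaving out ob_Cd2 replicate 5 turned 645 higher and 134 lower into 1222 and 558, so that library moves the balance. What the choice of model adds was not tested.

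Of the 39 lists, 7 passed with the preset correlation and 3 with an estimated one. NRF2 and glutathione genes had 18 of 25 members higher (23 higher and 0 lower adjusted over the list alone, median log2 change 0.74, adjusted p = 2.74e-61, and adjusted p = 7.1e-06 with an estimated correlation), among them Gsta4 (2.35 ± 0.21). Metal handling genes had 7 higher and 1 lower of 15 (median log2 change 0.55, 10 higher and 1 lower adjusted over the list alone, adjusted p = 3.13e-20 or adjusted p = 4.3e-09 with an estimated correlation), among them the zinc exporter Slc30a2 (1.06 ± 0.14). Lysosome and autophagy genes had 10 of 24 higher (median log2 change 0.29, 12 higher and 0 lower adjusted over the list alone, adjusted p = 1.97e-12 or adjusted p = 0.00552 with an estimated correlation), among them Ctsd (0.89 ± 0.13), Ctsl (0.53 ± 0.07) and Lamp1 (0.40 ± 0.05). The remaining 4 passed only with the preset correlation, and where 2 adjusted p stand together the second is with an estimated correlation. Targets of p53 had 5 of 20 higher (adjusted p = 4.45e-06, or adjusted p = 0.749 with an estimated correlation), with Eda2r at 2.09 ± 0.26, Pmaip1 at 1.09 ± 0.27, Ccng1 at 0.92 ± 0.13 and Bax at 0.73 ± 0.16. Mitochondrially encoded genes had 3 of 13 higher (adjusted p = 1.92e-09 or 0.271), with mt-Nd2 at 0.84 ± 0.16. Interferon genes had 3 of 26 higher (adjusted p = 0.00144 or 0.831), with Bst2 at 0.98 ± 0.15. Podocyte genes had 2 of 11 lower (adjusted p = 0.00186 or 0.271). The preset correlation gave 11 lists without ob_Cd2 replicate 5. With an estimated one, its removal gave calls to the mitochondrially encoded (adjusted p = 0.0272) and p53 target (adjusted p = 0.025) lists.

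The difference between genotypes in the response to 0.5 mg/kg was tested directly. The rise of Hmox1 was larger in ob by 3.27 ± 0.23 (adjusted p = 1.43e-11), and its level at this dose was higher in ob than in b6j mice by 2.49 (adjusted p = 4.59e-13). Gstm3 differed by 3.94 ± 0.75 (adjusted p = 0.00584), Mas1 by 3.53 ± 0.53 (adjusted p = 0.000213), and Ly6f by 3.32 ± 0.66 (adjusted p = 0.0085). Eda2r differed by 2.05 ± 0.40 (adjusted p = 0.00831), Gdf15 by 1.98 ± 0.35 (adjusted p = 0.0026), Cbr3 by 1.82 ± 0.29 (adjusted p = 0.000522) and Slc30a2 by 0.94 ± 0.19 (adjusted p = 0.0142). Mt1 rose more in ob by 1.10 ± 0.19 (adjusted p = 0.00123), while the interaction of Mt2 was not called (1.06 ± 0.38, adjusted p = 0.359). Neither was that of Lcn2 (-0.02 ± 1.10, adjusted p = 0.999) or Lep (-1.13 ± 1.64, adjusted p = 0.947, or -2.96 and still not called without ob_Cd0.5 replicate 2). Gstm3 (4.03, adjusted p = 0.105) and Ly6f (3.48, adjusted p = 0.115) were not called with limma-voom.

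Of 3 further interactions, 2 have calls and 1 a size that depend on single mice. Havcr1 (4.92 ± 1.15, adjusted p = 0.0385) lost its call on leaving out any 1 of 16 of the 24 libraries: each ob control, ob_Cd0.5 replicates 3 to 6 and b6j_Cd0.5 replicates 1 to 4 and 6 (adjusted p = 0.05 to 0.0857), and b6j_control replicate 4, without which it stood at 2.31 (adjusted p = 0.261). Gsta1 (3.61 ± 0.78, adjusted p = 0.0232) stood at 1.86 (adjusted p = 0.539) without that same library. Popdc3 (7.11 ± 1.02, adjusted p = 0.000122) moved to 9.36 without ob_control replicate 4 and to 6.4 without b6j_control replicate 3. Gsta1 (2.28, adjusted p = 0.438) and Havcr1 (2.60, adjusted p = 0.292) were not called with limma-voom. Havcr1 (4.23, adjusted p = 0.17) was not called with the replicate block.

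In total 70 of 18180 genes had a called interaction, 67 higher and 3 lower in ob, 41 of them above 2-fold. The count was 254 without ob_Cd2 replicate 5 (202 higher, 52 lower, 80 above 2-fold), 45 without ob_control replicate 1, 44 without ob_control replicate 2 and 45 without b6j_Cd0.5 replicate 1. The share of called genes that rose was 95.7%, against 76.4% with limma-voom sample weights and 79.1% with a fit to the compared groups alone, so the balance of rises and falls is not settled. With the model unchanged, leaving out ob_Cd2 replicate 5 turned 67 higher and 3 lower into 202 and 52, so that library moves the balance. What the choice of model adds was not tested. The 3 lower genes were Rasl11a (-0.87 ± 0.19, adjusted p = 0.0249), Npl (-0.71 ± 0.16, adjusted p = 0.0346) and Pdk1 (-0.47 ± 0.10, adjusted p = 0.0229). Rasl11a lost its call without ob_control replicate 6 (-0.82, adjusted p = 0.0552), b6j_Cd0.5 replicate 3 (-0.85, adjusted p = 0.0542), and Pdk1 without ob_control replicate 2 (-0.45, adjusted p = 0.0501), b6j_Cd0.5 replicate 1 (-0.45, adjusted p = 0.0512). Npl lost it on leaving out any 1 of 11 of the 24 libraries: ob_control replicates 1, 5 and 6, ob_Cd0.5 replicates 2, 5 and 6, b6j_control replicates 3 and 5, or b6j_Cd0.5 replicates 2, 5 and 6 (adjusted p = 0.0508 to 0.0802). Npl (-0.71, adjusted p = 0.0579) was not called with the replicate block.

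Lists past the threshold numbered 10 with the preset correlation and 3 with an estimated one. NRF2 and glutathione genes rose more in ob, with 5 of 25 called (16 higher and 0 lower adjusted over the list alone, median log2 change 0.57, adjusted p = 3.56e-32, and adjusted p = 0.00122 with an estimated correlation), and metal handling genes likewise, with 2 of 15 (median log2 change 0.33, 5 higher and 0 lower adjusted over the list alone, adjusted p = 4.05e-05 or adjusted p = 0.00122 with an estimated correlation). Podocyte genes moved down in ob relative to b6j without any called member (median log2 change -0.33, 0 higher and 5 lower adjusted over the list alone, adjusted p = 9.81e-07 or adjusted p = 0.0198 with an estimated correlation). They were higher in ob than in b6j controls, which enter this test, so the difference before cadmium may add to it. Lysosome genes had 2 of 24 called higher, with adjusted p = 6.41e-05, or adjusted p = 0.234 with an estimated correlation. For p53 targets, 1 of 20 was called (adjusted p = 9.26e-05, or adjusted p = 0.879 with an estimated correlation). The other 5 lists had no called member and adjusted p of 0.547 to 0.903 with an estimated correlation. The preset correlation gave 17 lists without ob_Cd2 replicate 5.

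At 2 mg/kg the b6j response became broad. Hmox1 reached 1311 ± 333 CPM (28.7-fold above control, log2 4.84 ± 0.19, adjusted p = 2.01e-20, 6 of 6 above every control). Mt1 reached 3073 ± 582 CPM (26.6-fold, log2 4.73 ± 0.15, adjusted p = 1.32e-22, 6 of 6 above), with Mt2 at 5.21 ± 0.27. Ugt2b35 went from 0.133 ± 0.0631 to 96 ± 16.3 CPM (9.46 ± 0.47) and Gstm3 to 31.2 ± 13.4 CPM (7.25 ± 0.40). Other large rises were Ugt1a2 (6.26 ± 0.71), Ceacam3 (6.14 ± 0.41), Nyx (5.97 ± 0.41), Cbr3 (4.91 ± 0.23), Il1rn (4.78 ± 0.56) and Gsta1 (6.67 ± 0.56, or 8.40 without b6j_control replicate 4).

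Among the genes that fell, the vitamin D hydroxylase Cyp24a1 went from 195 ± 97.4 to 28.2 ± 15.2 CPM (-2.78 ± 0.40, adjusted p = 2.68e-06, 6 of 6 below every control). Ccl28 went from 36.4 ± 18.3 to 5 ± 1.48 CPM (-2.86 ± 0.29, adjusted p = 2.69e-09). The retinoic acid hydroxylase Cyp26b1 (-2.24 ± 0.58), Col27a1 (-2 ± 0.16), glucose-6-phosphatase G6pc (-1.88 ± 0.27), glycine decarboxylase Gldc (-1.88 ± 0.36), Cyp4a12a (-1.77 ± 0.24) and Slc16a14 (-1.76 ± 0.24) fell too. Havcr1 was called higher, at 159 ± 40.3 CPM (2.18 ± 0.70, adjusted p = 0.021), and the call depends on the controls: 4.79 (adjusted p = 4.51e-08) without b6j_control replicate 4, 1.97 (adjusted p = 0.0513) without b6j_control replicate 5 and 2.01 (adjusted p = 0.0505) without b6j_control replicate 6. Lcn2 was not called (1.48 ± 0.76, adjusted p = 0.163), though 6 of 6 mice lay above every control, and it was called without ob_Cd2 replicate 5, at 1.47 (adjusted p = 2.89e-07). The comparison called 4305 of 18180 genes, 2232 higher and 2073 lower, 1088 above 2-fold, and 6388 (3129 higher, 3259 lower, 1220 above 2-fold) without ob_Cd2 replicate 5. Havcr1 (2.19, adjusted p = 0.0577) was not called with the compared groups alone. Lcn2 (1.49, adjusted p = 7.46e-06) was called with the compared groups alone. Lcn2 (1.48, adjusted p = 4.79e-06) was called with limma-voom.

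Lists past the threshold numbered 16 with the preset correlation and 3 with an estimated one. Kept calls were those of NRF2 and glutathione genes with 21 of 25 higher (21 higher and 0 lower adjusted over the list alone, median log2 change 1.55, adjusted p = 1.7e-60, and adjusted p = 1.35e-05 with an estimated correlation). Metal handling genes followed with 8 higher and 1 lower of 15 (median log2 change 0.63, 8 higher and 2 lower adjusted over the list alone, adjusted p = 6.77e-11 or adjusted p = 4.77e-06 with an estimated correlation), and then inflammatory mediators with 15 higher and 1 lower of 24 (median log2 change 1.09, 15 higher and 2 lower adjusted over the list alone, adjusted p = 4.6e-09 or adjusted p = 0.0121 with an estimated correlation). Within them Abcc4 rose by 3.07 ± 0.16, the iron exporter Slc40a1 by 1.60 ± 0.16, C3 by 2.29 ± 0.27, Nfkb2 by 1.28 ± 0.12 and Relb by 1.19 ± 0.13, and Slc39a10 fell by 0.85 ± 0.13.

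The other 13 passed only with the preset correlation, and each adjusted p is given first with that one and then with an estimated one. Tubular injury genes had 18 of 30 higher (adjusted p = 2.06e-10 or 0.166, 21 higher and 1 lower adjusted over the list alone), with Fgg at 2.5 ± 0.39, Timp1 at 2.44 ± 0.35 and Gdf15 at 2.41 ± 0.25. Targets of p53 had 15 of 20 higher (adjusted p = 5.76e-12 or 0.166, 16 higher and 0 lower adjusted over the list alone), with Eda2r at 3.60 ± 0.28 and Plk2 at 1.95 ± 0.20. Cell cycle genes had 21 of 27 higher (adjusted p = 7.81e-08 or 0.214, 22 higher and 0 lower adjusted over the list alone), with Kif11 at 1.85 ± 0.32 and Ccna2 at 1.12 ± 0.19. Interferon genes had 20 of 26 higher (adjusted p = 2.33e-08 or 0.253, 21 higher and 0 lower adjusted over the list alone), with Bst2 at 1.38 ± 0.15. Macrophage genes had 13 of 20 higher (adjusted p = 7.25e-05 or 0.455, 15 higher and 0 lower adjusted over the list alone), with Mrc1 at 1.27 ± 0.25. Matrix genes had 15 of 26 higher (adjusted p = 1.27e-07 or 0.183, 22 higher and 0 lower adjusted over the list alone), with Fbn1 at 1.01 ± 0.19. Lysosome genes had 10 of 24 higher (adjusted p = 0.00238 or 0.285, 10 higher and 1 lower adjusted over the list alone), with Ctsd at 0.91 ± 0.13.

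On the falling side, nuclear-encoded respiratory chain genes had 28 of 32 lower (adjusted p = 2.29e-17 or 0.148, 0 higher and 32 lower adjusted over the list alone), with Ndufb10 at -0.51 ± 0.07 and Cox7a2 at -0.61 ± 0.07. Proximal tubule genes had 10 lower and 1 higher of 32 (adjusted p = 3.35e-06 or 0.586, 1 higher and 14 lower adjusted over the list alone), with Cyp4b1 at -1.63 ± 0.22 and the gluconeogenic Pck1 at -1.46 ± 0.19. Fatty acid oxidation genes had 11 of 30 lower (adjusted p = 0.0013 or 0.68, 0 higher and 11 lower adjusted over the list alone), with Acaa2 at -0.86 ± 0.17. Distal tubule genes had 5 of 11 lower (adjusted p = 0.00491 or 0.511, 0 higher and 5 lower adjusted over the list alone), with Calb1 at -0.84 ± 0.23. Clock genes had 6 of 18 lower (adjusted p = 0.0013 or 0.148, 1 higher and 6 lower adjusted over the list alone), with Hlf at -1.39 ± 0.21. Androgen-responsive genes had 4 of 10 lower (adjusted p = 0.0111 or 0.285, 0 higher and 4 lower adjusted over the list alone), with Odc1 at -1.42 ± 0.22. Lists passing with the preset correlation numbered 18 without ob_Cd2 replicate 5. Its removal with an estimated correlation gave calls to the tubular injury (adjusted p = 0.00737) and p53 target (adjusted p = 0.00201) lists.

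**Figure D3:**
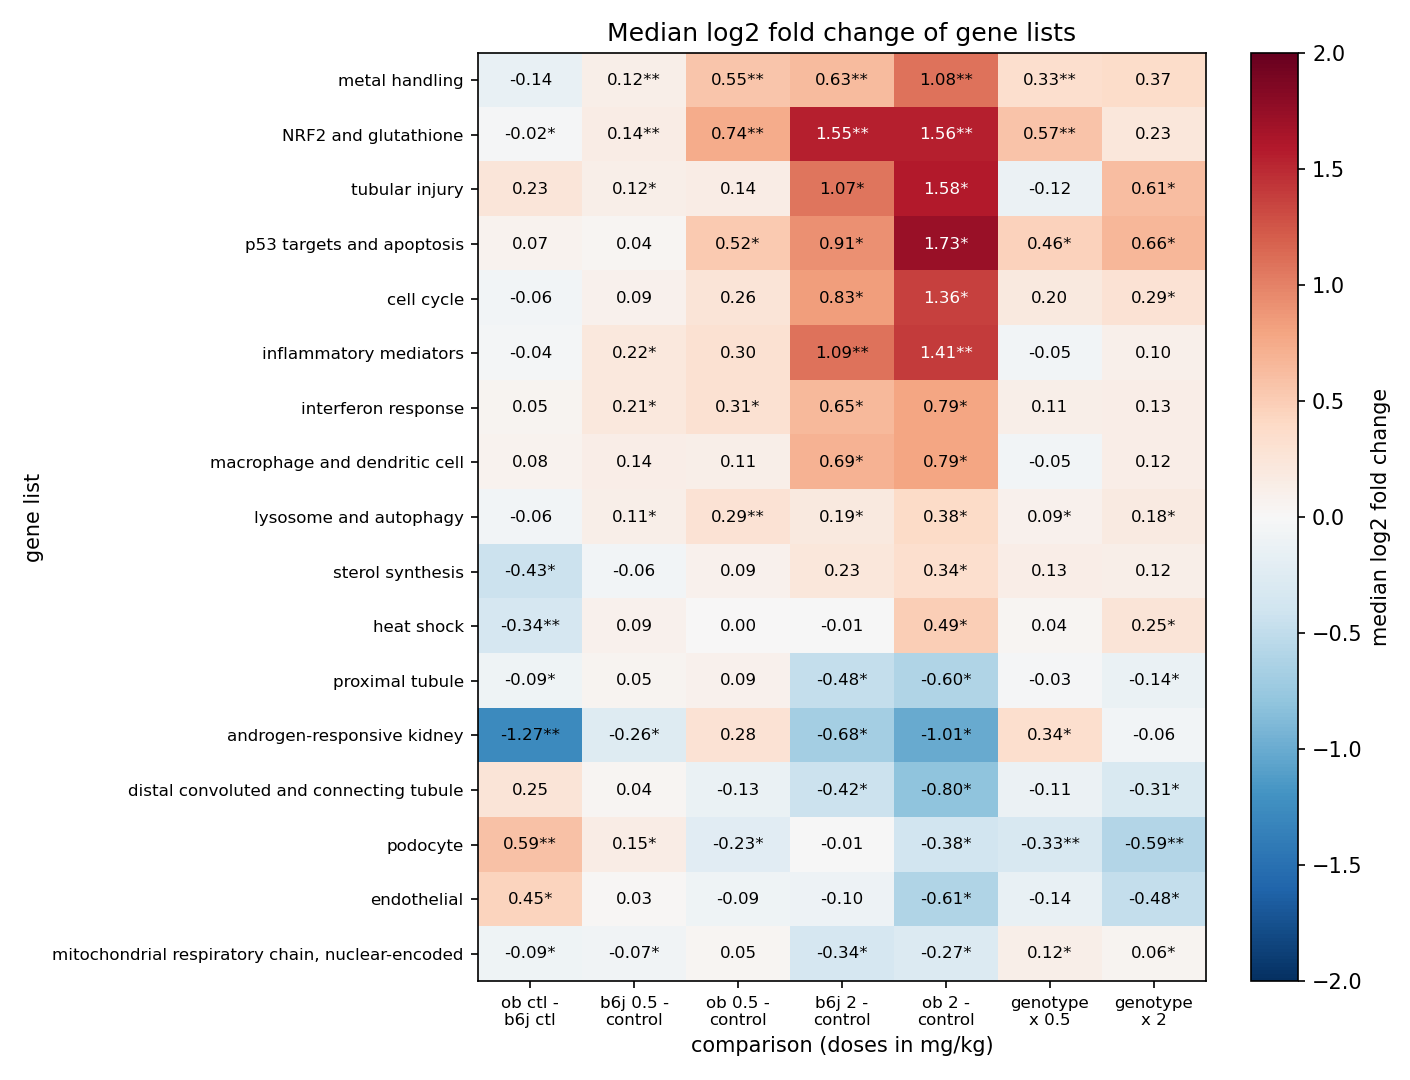
Median log2 change of the members of each gene list in each comparison. 1 star marks an adjusted p of camera below 0.05 with the preset correlation between genes, and 2 stars mark lists that also pass with an estimated correlation.

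At 2 mg/kg the ob response was broad too. Hmox1 reached 1424 ± 390 CPM (53.6-fold above control, log2 5.74 ± 0.20, adjusted p = 4.42e-22, 6 of 6 above every control). Mt1 reached 4424 ± 518 CPM (39.8-fold, log2 5.31 ± 0.16, adjusted p = 6.77e-24) and Mt2 rose by 5.81 ± 0.27. Havcr1 reached 201 ± 179 CPM from a control level near 1 (7.91 ± 0.98, adjusted p = 7.38e-08, 6 of 6 above). Ugt2b35 reached 150.4 ± 87.6 CPM (9.65 ± 0.45), Gstm3 63.8 ± 25.1 CPM (7.85 ± 0.39) and Popdc3 16.1 ± 10.4 CPM. Gsta1 (7.29 ± 0.56), Il1rn (5.34 ± 0.59), Eda2r (4.73 ± 0.28), Cbr3 (4.25 ± 0.21) and Gdf15 (3.63 ± 0.27) followed.

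Of the genes named here, Cyp24a1 fell most, from 545 ± 177 to 50.0 ± 12.1 CPM (-3.45 ± 0.41, adjusted p = 4.36e-08, 6 of 6 below every control). Next came the transporters Slco1a1 (-3.14 ± 0.45) and Slco4c1 (-2.26 ± 0.30), Mettl7a2 (-2.89 ± 0.36), Ceacam2 (-2.83 ± 0.33), Slitrk6 (-2.53 ± 0.38), C8a (-2.47 ± 0.36) and Akr1c18 (-2.45 ± 0.55). Lcn2 rose by 5.86 ± 0.86 (adjusted p = 1.73e-06), but its mean of 278 ± 627 CPM was made by ob_Cd2 replicate 5 at 1558 CPM, and without that library the rise was 2.19 (adjusted p = 1.06e-10). Pdk4 behaved the same way (4.41 ± 0.84, adjusted p = 7.72e-05) and lost its call without ob_Cd2 replicate 5 (0.60, adjusted p = 0.0771). The comparison called 6976 of 18180 genes, 3708 higher and 3268 lower, 1886 above 2-fold. Without ob_Cd2 replicate 5 it called 6989 (3514 higher, 3475 lower, 1575 above 2-fold), of which 5855 were the same genes. A fit to the compared groups alone called 3880 here, fewer than the 6061 it called in b6j at this dose, so which genotype has the higher count is not settled. Akr1c18 (-2.76, adjusted p = 0.219) and Pdk4 (0.73, adjusted p = 0.0559) were not called with limma-voom.

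Lists past the threshold numbered 26 with the preset correlation and 3 with an estimated one. NRF2 and glutathione genes had 22 of 25 higher (23 higher and 0 lower adjusted over the list alone, median log2 change 1.56, adjusted p = 6.28e-45, and adjusted p = 0.000136 with an estimated correlation). Metal handling genes had 10 higher and 2 lower of 15 (median log2 change 1.08, 11 higher and 2 lower adjusted over the list alone, adjusted p = 2.6e-10 or adjusted p = 4.8e-06 with an estimated correlation). Inflammatory mediators had 17 higher and 2 lower of 24 (median log2 change 1.41, 18 higher and 2 lower adjusted over the list alone, adjusted p = 6.77e-08 or adjusted p = 0.0288 with an estimated correlation). Gsta4 rose by 3.24 ± 0.21, Slc40a1 by 1.42 ± 0.15, C3 by 2.18 ± 0.26 and Nfkb2 by 1.19 ± 0.12.

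Other lists passed only with the preset correlation, and each adjusted p is given first with that one and then with an estimated one. Tubular injury genes had 26 of 30 higher and 1 lower (adjusted p = 6.55e-12 or 0.14, 28 higher and 1 lower adjusted over the list alone), with Timp1 at 3.18 ± 0.36 and Cd44 at 2.48 ± 0.31. Targets of p53 had 16 of 20 higher (adjusted p = 2.76e-16 or 0.0952, 16 higher and 0 lower adjusted over the list alone), with Plk2 at 2.43 ± 0.20, Bbc3 at 2.09 ± 0.19 and Ccng1 at 2.06 ± 0.13. Cell cycle genes had 21 of 27 higher (adjusted p = 3.29e-09 or 0.181, 22 higher and 1 lower adjusted over the list alone), with Kif11 at 2.20 ± 0.33. Endothelial genes had 14 of 14 lower (adjusted p = 2.14e-07 or 0.215, 0 higher and 14 lower adjusted over the list alone), with Kdr at -1.07 ± 0.11 and Flt1 at -0.62 ± 0.08. Podocyte genes had 5 of 11 lower (adjusted p = 0.000674 or 0.14, 0 higher and 6 lower adjusted over the list alone). Proximal tubule genes had 16 of 32 lower (adjusted p = 1.56e-07 or 0.366, 0 higher and 19 lower adjusted over the list alone), with Slc27a2 at -1.37 ± 0.13. The fall was not particular to them. Mean changes were -0.69 for this list, -0.76 for distal tubule, -0.62 for intercalated cell, -0.54 for thick ascending limb and -0.54 for principal cell genes. They were 0.93 for macrophage and 0.51 for T and NK cell genes. Lysosome genes had 15 higher and 3 lower of 24 (adjusted p = 2.73e-06 or 0.0952, 15 higher and 3 lower adjusted over the list alone), with Ctsd at 1.58 ± 0.13. All 23 lists that lost their call had adjusted p between 0.0952 and 0.639 with an estimated correlation. Within the group, ob_Cd2 replicate 5 lay below the other 5 libraries in 30 of 32 proximal tubule and 14 of 14 endothelial genes, and above them in 24 of 30 tubular injury and 20 of 20 p53 genes. Without it the median changes went from -0.60 to -0.46, -0.61 to -0.44, 1.58 to 1.08 and 1.73 to 1.33 in that order. Lists passing with the preset correlation numbered 24 without ob_Cd2 replicate 5, and calls were lost by the unfolded protein response (adjusted p = 0.116) and immediate early (adjusted p = 0.223) lists. Its removal with an estimated correlation ended the call of the inflammatory mediator (adjusted p = 0.0515) list and gave calls to the tubular injury (adjusted p = 0.0105) and p53 target (adjusted p = 0.000816) lists.

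Between the doses in b6j mice, the metallothionein response had, on the log2 scale, mostly been reached at 0.5 mg/kg while the stress response had not. From 0.5 to 2 mg/kg Mt1 rose a further 1.17 ± 0.13 (adjusted p = 5.82e-08), and Mt2 1.37 ± 0.21. Hmox1 rose by 3.49 ± 0.18 (adjusted p = 1.15e-16, 6 of 6 above every mouse at 0.5 mg/kg). Havcr1 rose by 2.93 ± 0.73 (adjusted p = 0.00411, 6 of 6 above) and Lcn2 was not called (1.20 ± 0.75, adjusted p = 0.295, 6 of 6 above), but was without ob_Cd2 replicate 5, at 1.20 (adjusted p = 1.25e-05). Ugt2b35 (6.48 ± 0.37), Ly6f (5.20 ± 0.43), Ceacam3 (5.14 ± 0.38), Gsta1 (5.03 ± 0.50), Gstm3 (4.68 ± 0.32) and Cbr3 (4.20 ± 0.21) were among the largest rises of called genes with a mean of at least 5 CPM. Cyp24a1 (-1.93 ± 0.39), Gldc (-1.89 ± 0.36), Cyp2d12 (-1.88 ± 0.32), Col27a1 (-1.70 ± 0.16), Cyp4b1 (-1.58 ± 0.22), G6pc (-1.46 ± 0.26) and Angptl7 (-1.44 ± 0.28) were among the largest falls of such genes. Called genes numbered 3143, 1596 higher and 1547 lower, or 5267 (2489 higher, 2778 lower, 911 above 2-fold) without ob_Cd2 replicate 5. NRF2 and glutathione genes had 21 of 25 higher (22 higher and 0 lower adjusted over the list alone, median log2 change 1.43, adjusted p = 5.14e-59, and adjusted p = 2.67e-05 with an estimated correlation). Metal handling had 6 of 15 (median log2 change 0.45, 7 higher and 0 lower adjusted over the list alone, adjusted p = 2.93e-05 or adjusted p = 0.00141 with an estimated correlation). Inflammatory mediators had 11 higher and 1 lower of 24 (median log2 change 0.86, 14 higher and 1 lower adjusted over the list alone, adjusted p = 5.18e-08 or adjusted p = 0.0223 with an estimated correlation). These 3 of 16 lists kept their call with an estimated correlation. With ob_Cd2 replicate 5 left out, 18 lists passed with the preset correlation. Leaving it out with an estimated correlation gave calls to the tubular injury (adjusted p = 0.0096), proximal tubule (adjusted p = 0.0283), p53 target (adjusted p = 0.00102) and clock (adjusted p = 0.0372) lists. Lcn2 (1.22, adjusted p = 0.000121) was called with the compared groups alone. Lcn2 (1.09, adjusted p = 0.000256) was called with limma-voom.

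In ob mice the step from 0.5 to 2 mg/kg raised Hmox1 by 1.12 ± 0.16 (adjusted p = 5.37e-06), Mt1 by 0.65 ± 0.13 (adjusted p = 0.000381) and Mt2 by 0.90 ± 0.20. Havcr1 rose by 3.74 ± 0.76 (adjusted p = 0.000363, 6 of 6 above every mouse at 0.5 mg/kg). Ly6f rose by 3.55 ± 0.38, Eda2r by 2.64 ± 0.24, Timp1 by 2.12 ± 0.33, Plk2 by 1.91 ± 0.20 and Cbr3 by 1.72 ± 0.19. Lcn2 rose by 5.6 ± 0.85, Krt20 by 5.23 ± 0.88 and Flnc by 4.04 ± 0.73, which became 1.94, 2.26 and 2.29 without ob_Cd2 replicate 5. Slco1a1 (-3.73 ± 0.46), Akr1c18 (-2.56 ± 0.55), Ceacam2 (-2.55 ± 0.33), Mettl7a2 (-2.50 ± 0.36), C8a (-2.33 ± 0.36), Cyp24a1 (-2.17 ± 0.39), Cyp4b1 (-1.93 ± 0.23) and Dpys (-1.90 ± 0.26) were among the largest falls of called genes with a mean of at least 5 CPM. Called genes numbered 5406, 2772 higher and 2634 lower, and 5080 (2460 higher, 2620 lower, 935 above 2-fold) without ob_Cd2 replicate 5, 4172 of the total shared. Inflammatory mediators, 15 higher and 2 lower of 24 (18 higher and 2 lower adjusted over the list alone, median log2 change 0.95, adjusted p = 8.52e-09, and adjusted p = 0.0455 with an estimated correlation), were the only list of 23 to keep its call with an estimated correlation. With ob_Cd2 replicate 5 left out, 22 lists passed with the preset correlation, and calls were lost by the thick ascending limb (adjusted p = 0.0779), podocyte (adjusted p = 0.0808), unfolded protein response (adjusted p = 0.403) and immediate early (adjusted p = 0.0812) lists. Leaving it out with an estimated correlation gave calls to the NRF2 and glutathione (adjusted p = 0.0287), tubular injury (adjusted p = 0.00745), proximal tubule (adjusted p = 0.0287), macrophage (adjusted p = 0.0411), p53 target (adjusted p = 0.00745) and androgen-responsive (adjusted p = 0.0287) lists. Akr1c18 (-2.88, adjusted p = 0.24) was not called with limma-voom.

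Several of the largest differences between genotypes in the response to 2 mg/kg lay in genes that already differed before cadmium, and the same control mice enter both tests. Prlr fell in ob mice, from 113 ± 16.4 to 28.7 ± 10.8 CPM, while b6j went from 6.05 ± 4.40 to 15.2 ± 5.58 CPM (interaction -3.31 ± 0.45, adjusted p = 4.75e-05). Slc7a12 (-2.90 ± 0.71, adjusted p = 0.0233), Kynu (-2.65 ± 0.59, adjusted p = 0.0116) and the Ugt1a members Ugt1a2 (-4.03 ± 0.88) and Ugt1a10 (-3.31 ± 0.46), all higher in ob controls, also had interactions below 0, although Ugt1a2 rose in ob mice too (2.23 ± 0.46, against 6.26 ± 0.71 in b6j). Ceacam2 (-2.63 ± 0.44), Mettl7a2 (-2.55 ± 0.49) and Slco4c1 (-2.39 ± 0.41) had interactions below 0 as well, and each fell in ob. In the other direction Ccl28, already low in ob controls, fell in b6j and stayed at 2.03 ± 0.705 CPM in ob (interaction 2.67 ± 0.42, adjusted p = 0.000359), and Ces2b rose more in ob (3.04 ± 0.44, adjusted p = 9.03e-05). Kynu (-2.63, adjusted p = 0.059) and Slc7a12 (-2.89, adjusted p = 0.0702) were not called with the compared groups alone. Ugt1a2 (-3.84, adjusted p = 0.228) was not called with limma-voom.

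Havcr1 rose more in ob (5.73 ± 1.13, adjusted p = 0.00446), by 3.13 (adjusted p = 0.018) without b6j_control replicate 4. It started lower in ob than in b6j controls (-5.38, or -2.78 without that library), and those controls enter this test. The larger rise therefore does not place ob above b6j mice at 2 mg/kg, and the levels at that dose were not tested against each other. Zbtb16 rose more in ob (2.57 ± 0.48, adjusted p = 0.00242, or 1.95 without ob_Cd2 replicate 5). The larger rises of Lcn2 (4.38 ± 1.08, adjusted p = 0.0252) and Pdk4 (4.87 ± 1.09, adjusted p = 0.0122) were not called without ob_Cd2 replicate 5, at 0.72 (adjusted p = 0.153) and 1.07 (adjusted p = 0.098). Mt1 was not called (0.58 ± 0.19, adjusted p = 0.0948), though it was without ob_control replicate 4 (0.70, adjusted p = 0.0379), b6j_Cd2 replicate 2 (0.67, adjusted p = 0.0493). Mt2 (0.59 ± 0.38, adjusted p = 0.439) and Lep (-2.12 ± 1.61, adjusted p = 0.522) were not called. Hmox1 was called (0.90 ± 0.23, adjusted p = 0.0289), a call that ended without ob_Cd2 replicate 3 (0.76, adjusted p = 0.0636), b6j_control replicate 4 (0.74, adjusted p = 0.0537), b6j_Cd2 replicate 4 (0.83, adjusted p = 0.0545), b6j_Cd2 replicate 5 (0.86, adjusted p = 0.052). It too started lower in ob controls (-0.78), so the same limit holds. Havcr1 (2.66, adjusted p = 0.249) and Lcn2 (0.61, adjusted p = 0.318) were not called with limma-voom. Hmox1 (0.92, adjusted p = 0.0883), Lcn2 (4.41, adjusted p = 0.0937) and Pdk4 (4.90, adjusted p = 0.0615) were not called with the compared groups alone. Lcn2 (2.65, adjusted p = 0.215) and Pdk4 (3.06, adjusted p = 0.171) were not called with the replicate block. Mt1 (0.61, adjusted p = 0.0351) was called with DESeq2. Mt1 (0.57, adjusted p = 0.035) was called with limma-voom.

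Called interactions numbered 376 of 18180 genes, 193 higher and 183 lower in ob, 136 above 2-fold. The count was 758 without ob_Cd2 replicate 5 (404 higher, 354 lower, 156 above 2-fold), with 358 shared, 748 without ob_Cd2 replicate 6, 216 without b6j_control replicate 3, 246 without b6j_control replicate 5 and 244 without b6j_Cd2 replicate 1. Of 18 lists past the preset test, 1 kept its call with an estimated correlation: podocyte genes moved down in ob relative to b6j, 3 of 11 (0 higher and 6 lower adjusted over the list alone, median log2 change -0.59, adjusted p = 4.66e-07, and adjusted p = 0.0484 with an estimated correlation), with Podxl at -0.64 ± 0.11. Their mean change at 2 mg/kg was -0.46 in ob and 0.04 in b6j. Podocyte and endothelial genes were both higher in ob than in b6j controls, and those controls enter this test. The difference before cadmium may therefore add to both interactions. Endothelial genes had 5 of 14 lower (adjusted p = 1.4e-10, or adjusted p = 0.192 with an estimated correlation), with Kdr at -0.80 ± 0.15 and Flt1 at -0.46 ± 0.11. Tubular injury genes had 4 of 30 higher (adjusted p = 0.00163, or adjusted p = 0.585 with an estimated correlation), and adjusted p = 0.375 with the preset correlation without ob_Cd2 replicate 5. Lists passing with the preset correlation numbered 14 without ob_Cd2 replicate 5, and calls were lost by the tubular injury (adjusted p = 0.375), proximal tubule (adjusted p = 0.521), distal tubule (adjusted p = 0.0806), principal cell (adjusted p = 0.0901), matrix (adjusted p = 0.416), cell cycle (adjusted p = 0.128) and glucocorticoid target (adjusted p = 0.129) lists. Flt1 (-0.44, adjusted p = 0.0537) was not called with the compared groups alone.

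**Figure D4:**
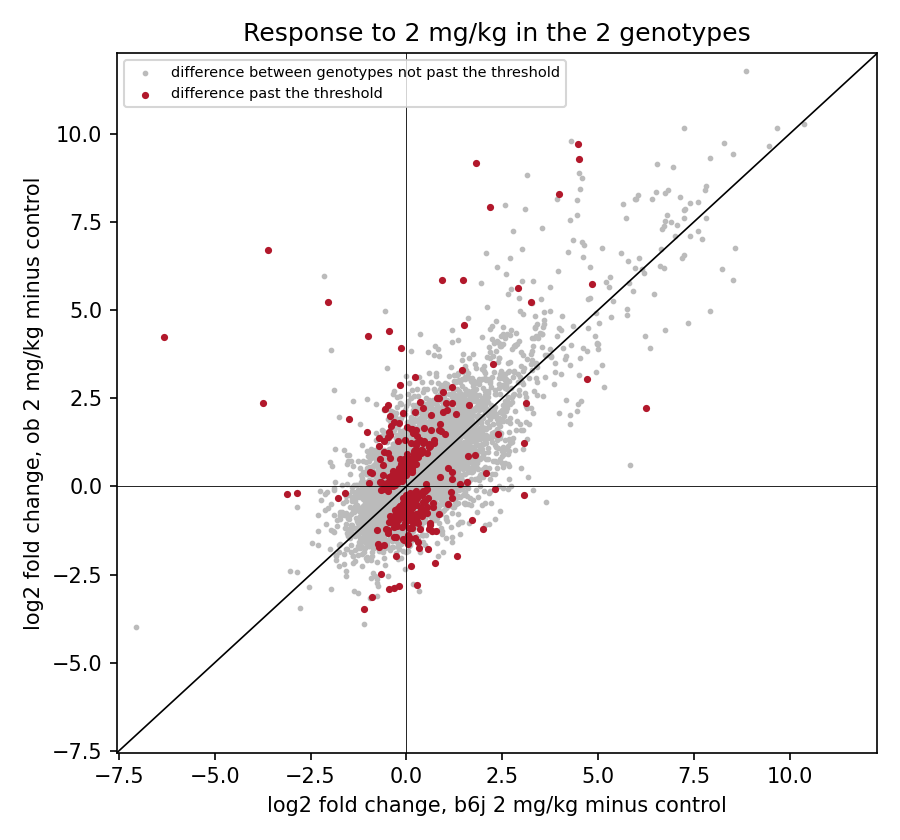
Log2 change from control at 2 mg/kg in ob mice against that in b6j mice for each tested gene. Red marks genes with a called interaction.

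The 2 genotypes shared much of the response to 2 mg/kg. Of the genes called in each, 3057 moved the same way (1648 up, 1409 down, against 455.2 and 372.6 for independent lists of those sizes) and 26 moved opposite ways. Log2 changes of all 18180 genes correlated at 0.763 (rank correlation 0.615), and without ob_Cd2 replicate 5 4264 genes were shared, 57 moved opposite ways and the correlation was 0.775. Mt1, Hmox1, Gstm3, Ugt2b35 and Cyp24a1 are among them. At 0.5 mg/kg 48 genes were shared (46 up, 2 down, against 1.9 and 0), and the correlation was 0.328 (rank correlation 0.139). Without ob_Cd2 replicate 5 the shared genes there numbered 104 (97 up, 7 down), 2 moved opposite ways and the correlation was 0.316. No mouse enters both genotypes, so these figures have no shared control.

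Within a genotype the 2 doses share their controls, which alone makes their changes correlate. In ob mice 674 of the 779 genes called at 0.5 mg/kg moved the same way at 2 mg/kg (565 up, 109 down, against 131.6 and 24.1 for independent lists), with a correlation of 0.704 and a covariance of 0.364. Simulated groups with no change gave a correlation of 0.499 and a covariance of 0.033. With 3 different controls for each dose, the median of 20 divisions was 277 shared genes (251 to 302) and a correlation of 0.504. Without ob_Cd2 replicate 5, 1411 were shared. In b6j mice all 59 genes called at 0.5 mg/kg moved the same way at 2 mg/kg (54 up, 5 down, against 6.6 and 0.6), with a correlation of 0.47 and a covariance of 0.141, against 0.502 and 0.034 in simulated groups. With divided controls 25 genes (22 to 33) were shared at a correlation of 0.206.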

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

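The first pattern is ob_Cd2 replicate 5, and here the tests of an animal without cadmium, of a b6j animal and of degradation were chosen only after the result was seen: its lists stood away from the other 5 libraries of its group by a median of 1.68 for tubular injury, 1.45 for p53 targets, 1.78 for glucocorticoid targets, -2.60 for proximal tubule and -2.24 for macrophage genes. In a library of an animal given no cadmium the genes raised over 2-fold in b6j at 0.5 mg/kg would lie within 0.5 of the ob controls, but their median distance was 2.78, 28 of 35 lay above all 12 controls and Mt1 was 5414 against 150.2 CPM in the highest control, which argues against it. A library of a b6j animal would lie near 0 on a scale from the b6j mean at 2 mg/kg (0) to the other 5 libraries (1), but 10 genotype genes over 4-fold gave 0.74 (quartiles 0.55 to 1.32), just short of the bound of 0.75, and 23 over 2-fold, a set chosen after that, gave 1.06 (quartiles 0.58 to 1.64), which argues against it with moderate weight. Gene length explained 0.123% of the variance of its difference, which argues against RNA degradation read as a loss of long genes. The difference correlated with the b6j response at 2 mg/kg at 0.068 over 14099 genes (0.135 by rank), under the bound of 0.1 set for the first before it was seen, and while its tubular injury, p53 and proximal tubule lists moved as the b6j means did (1.23, 1.13 and -0.56), its macrophage (b6j mean 0.76), matrix (-1.71 against 0.74), fatty acid oxidation (1.21 against -0.26), mitochondrially encoded (-1.38 against 0.24) and clock lists (0.52 against -0.34) moved the other way, which argues against an animal simply further along the same response. Further lists went each way. The distal tubule, intercalated cell, principal cell, androgen-responsive, immediate early, cell cycle and respiratory chain lists moved as the b6j means did. The T and NK cell, mesangial, sterol synthesis, interferon, inflammatory mediator and NRF2 lists moved the other way. These figures set a list median for the library against a list mean for b6j. On the first component, which followed dose, this library stood at 135.91, against 40.62 to 69.12 in the other 5. That goes with the explanation in part, though the component was computed with this library in it. Another injury or illness of this mouse stays open and untested.

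The second pattern is the larger response of ob than of b6j mice at 0.5 mg/kg, 67 genes with a median interaction of 1.16, and here all tests but that of gene length were chosen only after the result was seen. A lower level in ob controls alone would leave none of these genes called higher in ob than in b6j at 0.5 mg/kg, and 45 of 67 were, which argues against it as the only cause for those genes. The 67 were picked with the same libraries, which favours that outcome and weakens the argument. The remaining genes were called lower in ob controls in 22 of 22, but the way they were picked leaves hardly any other outcome, so for these a lower start stays open. Over all 67, 35 were called lower in ob controls (median log2 difference -0.46), so a lower start may add to the interaction in some of the 45 as well. The trend of the interaction on gene length gave the called genes a median shift of 0.068 over 64 genes, under 0.1 of their median interaction, which argues against gene length bias. A greater effective exposure of ob kidneys stays open: the Mt1 interaction of 1.1 (standard error 0.19) belongs to the pattern itself and so does not test it, that of Mt2 was not called (1.06, adjusted p = 0.359), and kidney cadmium was not measured in these data.

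The third pattern is the androgen-responsive list, lower in ob than in b6j controls, and all tests of this part were chosen only after the result was seen. A smaller share of proximal tubule RNA would lower proximal tubule genes that are not on the androgen list by at least 0.5 of its median of -1.27, and their median was -0.07 over 30 members, but the quartiles of -0.68 to 0.35 hold that bound, so it stays open. Female animals among the ob controls would show Xist above Ddx3y, but the lowest ratio of Ddx3y to Xist was 181, which rules it out. Lower androgen action in ob males stays open as well: 8 of 10 members called lower and 0 higher is the observation that prompted the idea, so it does not test it, and no hormone was measured.

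Single libraries far from the other 5 of their group were sought by the gap test of Dixon in 96 sets of 6 values, where chance alone gives about 1 in 20 if values are normal, and 15 were found: ob_Cd0.5 replicate 2 for total count in M reads (32.5), b6j_Cd0.5 replicate 6 for length slope (-0.1015), ob_Cd0.5 replicate 4 for Mt1 CPM (2026), ob_Cd2 replicate 5 for Mt1 CPM (5414), b6j_control replicate 4 for Havcr1 CPM (181), b6j_Cd0.5 replicate 5 for Havcr1 CPM (48.5), ob_Cd2 replicate 5 for Lcn2 CPM (1558), b6j_control replicate 4 for Hmox1 CPM (71.6), ob_Cd0.5 replicate 2 for Lep CPM (14.1), ob_control replicate 2 for Gstm3 CPM (0.551), b6j_Cd0.5 replicate 6 for Gstm3 CPM (2.16), ob_control replicate 4 for Popdc3 CPM (0.0888), ob_Cd2 replicate 5 for Popdc3 CPM (37.1), b6j_control replicate 6 for Prlr CPM (14.7), b6j_Cd0.5 replicate 2 for Ugt2b35 CPM (1.79). CPM entered without logs, some near absent, and for genes named in the text. So 15 of 96 cannot be weighed against 1 in 20.

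Group labels were exchanged at random between mice to see how often as many genes are called as with the real groups, a check chosen only after the counts were seen. If chance explains a count, 5% or more of the splits of the same libraries call as many genes as the real one, and if not, under 5% of the splits call as many genes. Of 100 groupings, the real one included, 1 called as many in each of 7 comparisons and 2 did so for each interaction (2%). Of the first 40, 2 did so for the interaction at 2 mg/kg, which met the bound of 5% before the number was raised. At 2 mg/kg 1 exchanged grouping called 484 genes against 376, and at 0.5 mg/kg 1 called 2153 against 70. The first gave the other genotype to 5 of 6 controls and 2 of 6 mice at 2 mg/kg of each genotype, and the second to 6 of 6 controls and 2 of 6 mice at 0.5 mg/kg of each, so each reads the genotype difference itself, and the next highest counts were 39 and 0. For interactions the exchange mixes mice of both genotypes in a group, and 2822 genes differ between the control genotypes. That difference enters the spread or the contrast, so the check cannot decide on chance for either interaction. Elsewhere the highest exchanged count was 516 between controls, 10 and 1565 in b6j at 0.5 and 2 mg/kg, 50 and 4083 in ob, and 945 and 3149 between doses in b6j and ob. Each of these groupings gave the other label to 1 or 5 of 6 mice in both groups, so it lies close to the real one. The median count of the exchanged groupings was 0 in each comparison.

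Interactions called between genotypes, 70 genes at 0.5 mg/kg and 376 at 2 mg/kg, included at 0.5 mg/kg Cbr3 1.82, Eda2r 2.05, Gdf15 1.98, Gsta1 3.61, Gstm3 3.94, Havcr1 4.92, Hmox1 3.27, Ly6f 3.32, Mas1 3.53, Mt1 1.10, Npl -0.71, Pdk1 -0.47, Popdc3 7.11, Rasl11a -0.87 and Slc30a2 0.94, and at 2 mg/kg Ccl28 2.67, Ceacam2 -2.63, Ces2b 3.04, Flt1 -0.46, Havcr1 5.73, Hmox1 0.90, Kdr -0.80, Kynu -2.65, Lcn2 4.38, Mettl7a2 -2.55, Pdk4 4.87, Podxl -0.64, Prlr -3.31, Slc7a12 -2.90, Slco4c1 -2.39, Ugt1a10 -3.31, Ugt1a2 -4.03 and Zbtb16 2.57. Under limma-voom the counts were 805 and 1075.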

How the results depend on the processing

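Counts of called genes moved by more than 1.5 times under these choices: 2822 between controls became 5629 with limma-voom, 5007 with the compared groups alone and 2257 to 4781 leaving out 1 library. In b6j at 0.5 mg/kg 59 became 97 with DESeq2, 232 with limma-voom, 120 with the compared groups alone and 42 to 157 leaving out 1 library, at 2 mg/kg 4305 became 6949 with limma-voom, and between doses 3143 became 5176 with limma-voom and 2378 to 5267 leaving out 1 library. In ob at 0.5 mg/kg 779 became 2337 with limma-voom, 1937 with the compared groups alone and 578 to 1780 leaving out 1 library, at 2 mg/kg 6976 became 3880 with the compared groups alone, and between doses 5406 became 1889 with the compared groups alone. The interaction went from 70 at 0.5 mg/kg to 147 with DESeq2, 805 with limma-voom, 321 with the compared groups alone and 44 to 254 leaving out 1 library, and from 376 at 2 mg/kg to 757 with DESeq2, 1075 with limma-voom, 239 with no filter, 194 with the compared groups alone and 216 to 758 leaving out 1 library. Lists past the threshold with an estimated correlation numbered 3, 2, 3, 3, 3, 3, 1, 3 and 1 in the 9 comparisons in the order control, b6j 0.5, b6j 2, b6j doses, ob 0.5, ob 2, ob doses and the interactions. With the preset correlation they numbered 12, 12, 16, 16, 7, 26, 23, 10 and 18 in that order, and 15, 13, 18, 18, 11, 24, 22, 17 and 14 without ob_Cd2 replicate 5. With divided controls the doses shared 277 genes in ob and 25 in b6j. With all 6 controls for both doses the count in ob went from 674 to 1411 without ob_Cd2 replicate 5. Replicate numbers do not pair mice across groups (correlations of residuals at the same number -0.184 to 0.242, and in no pair of groups did more than 3 of 6 libraries correlate best with their own number), and with replicate number as a replicate block the counts were 2692, 58, 4161, 2898, 745, 6767, 5038, 67 and 322 in that order. Of the 256 named gene values with an adjusted p from DESeq2, 0 lost and 1 gained a call with it, and of 269 values 16 lost and 3 gained one with limma-voom, 5 lost one with the replicate block, 3 lost and 2 gained one without ob_Cd2 replicate 5, 4 lost one without b6j_control replicate 4, and none changed with RLE size factors. With the compared groups alone 11 lost and 2 gained one of 262. Named genes were picked in part for calls that hold, so these tallies say nothing on called genes at large. Calls lost with limma-voom were in controls Havcr1 -3.15, Lep 4.79, in b6j 0.5 Gstm3 2.40, Ugt1a2 3.68, Ugt2b35 2.85, in b6j 2 Star 0.59, in ob 2 Akr1c18 -2.76, Pdk4 0.73, in ob doses Akr1c18 -2.88, in interaction 0.5 Gsta1 2.28, Gstm3 4.03, Havcr1 2.60, Ly6f 3.48, in interaction 2 Havcr1 2.66, Lcn2 0.61, Ugt1a2 -3.84. Calls gained were in b6j 2 Lcn2 1.48, in b6j doses Lcn2 1.09, in interaction 2 Mt1 0.57. With the compared groups alone, lost were in b6j 0.5 Dock5 -0.29, Nyx 2.53, in b6j 2 Havcr1 2.19, Star 1.18, in ob 2 Egf -1.10, in interaction 2 Flt1 -0.44, Hmox1 0.92, Kynu -2.63, Lcn2 4.41, Pdk4 4.90, Slc7a12 -2.89, and gained in b6j 2 Lcn2 1.49, in b6j doses Lcn2 1.22. Lost with the replicate block were in b6j 2 Star 0.82, in interaction 0.5 Havcr1 4.23, Npl -0.71, in interaction 2 Lcn2 2.65, Pdk4 3.06, and gained with DESeq2 was in interaction 2 Mt1 0.61. The cause was not tested. No named gene changed sign in a called direction under the settings tallied here, but with 1 library left out Star in b6j at 2 mg/kg went from 1.17 to -0.03.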

Other observations

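Further single genes were called. In ob kidneys at 2 mg/kg the epidermal growth factor precursor Egf fell by 1.12 ± 0.34, the cortisol-inactivating Hsd11b2 by 0.72 ± 0.11 and the water channel Aqp3 by 0.78 ± 0.13, while Asns rose by 2.05 ± 0.32 and Phgdh by 1.56 ± 0.20. At 2 mg/kg the clock output factor Hlf fell by 2.18 ± 0.22 in ob and 1.39 ± 0.21 in b6j, Vegfa by 0.85 ± 0.12 and 0.58 ± 0.12, and Errfi1 by 1.20 ± 0.14 and 1.23 ± 0.14. All of these are called by the edgeR test with 6 mice per group, but Egf was not with a fit to the compared groups alone, at -1.10 (adjusted p = 0.147).

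Carbonic anhydrase Car3 rose in ob kidneys by 2.08 ± 0.31 at 0.5 mg/kg (adjusted p = 1.23e-05, 6 of 6 above every control) and by 2.49 ± 0.31 at 2 mg/kg (adjusted p = 8.02e-08). In b6j mice at 2 mg/kg the adrenal hydroxylase Cyp21a1 read 6.72 ± 1.21 (adjusted p = 0.000106, 5 of 6 above every control) and 3.75 (adjusted p = 0.00249) without b6j_Cd2 replicate 3. Star read 1.17 ± 0.37 (adjusted p = 0.0193) and -0.03 (adjusted p = 0.925) without it, and was not called with limma-voom, at 0.59 (adjusted p = 0.17), the compared groups alone, at 1.18 (adjusted p = 0.094), or the replicate block, at 0.82 (adjusted p = 0.114). The mean score of the 3 adrenal genes was 4.302 in that library and 1.095 in b6j_Cd2 replicate 2, and 0.214 to 1.137 in the 6 ob libraries at 2 mg/kg against -0.468 to 0.191 in ob controls, with no test made on these scores.

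The mean share of reads on mitochondrial genes was 7.84%, 9.57% and 9.74% in ob mice at 0, 0.5 and 2 mg/kg and 7.82%, 8.49% and 9.25% in b6j mice, with no test made. In ob_Cd2 replicate 5 it was 5.995%, against 9.16 to 11.2% in the other 5 of that group.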
